A study of Mus musculus with 37 samples.

How the data were processed

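RNA bound to ribosomes of podocytes, the epithelial cells that wrap the capillaries of the kidney filter, was isolated by translating ribosome affinity purification (TRAP) and sequenced. The labels describe 37 mouse libraries, of which 36 are TRAP libraries and 1 is total RNA of whole kidney. Per the labels, libraries were made with a NuGEN Ovation kit for mouse after DNase treatment and fragmentation to 200 bp. The deposited tables hold raw counts per gene and FPKM for 32108 genes in the same 37 libraries. The submitters' processing notes name cutadapt 1.16, STAR, FastQC and featureCounts 1.15.2. The deposited FPKM equalled the count times a scale factor over gene length and library total, within 0.001 for 100% of the values. The notes give the mm9 genome build, but the coordinates in the tables were those of GRCm38: of 31871 genes matched by identifier to GENCODE release 21 for mouse, 99.981% overlapped their place on GRCm38 and 82.15% had the same chromosome, start and end. Positions are therefore given on GRCm38. Whether counting was done by strand is not given in the sources used here. Genes that overlap another gene on the opposite strand, and close paralogs, can share reads.

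Total counts per TRAP library ranged from 6702120 to 37786025, and the kidney library had 28033680 counts. Between 14320 and 21290 genes had a count above 0 in a TRAP library. The 18S ribosomal RNA gene Rn18s-rs5 took 1.43 to 18.4% of the counts, and genes of the mitochondrial chromosome took 0.295 to 1.31%. Reads carry no molecular identifiers, so counting intervals cover counting error only. The labels do not say that replicates are separate animals, so p-values measure the spread between libraries. Fisher's tests and list tests at the preset correlation compare genes instead.

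Libraries were grouped by model, age and diabetes as the labels give them. Counts were fitted in R 4.3.3 with edgeR 4.0.16: TMM normalization, the default filter on low counts by group, and robust quasi-likelihood F tests with Benjamini-Hochberg adjustment at 0.05. One fit held the 17 libraries of the type 2 model (17180 genes tested) and one held the 19 libraries of the type 1 model (16279 genes). A fit of all 36 TRAP libraries (18511 genes) served the comparisons between the models. A gene is called when its adjusted p is under 0.05. CPM values are normalised read counts scaled to library size. The single kidney library allows no test, so ratios to it use CPM plus 0.5 and its count carries an exact 95% Poisson interval.

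Before the data were examined, 32 gene lists were fixed: 22 lists of pathways and cell functions, podocyte identity among them, and 10 lists of markers of other kidney cell types. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 3) with a preset correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with a correlation estimated from the data, and fry, which asks whether the members move one way on balance and compares a list with no other genes. Of 320 list tests, the median, the mean and the direction of the test differed in sign in 50, of which 1 was called. Scores of cell markers, each the mean log2 CPM of a list, were compared between groups by exact two-sided permutation tests in a family of 44. Shared calls were compared with n1 × n2 / N by one-sided Fisher's exact tests.

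The genes named were also chosen by a rule fixed at that time. For each diabetic comparison it takes the 8 called genes with the largest rise and the 8 with the largest fall, among those with a mean CPM of at least 10 whose diabetic and control libraries did not overlap. It adds up to 4 members with the lowest p of each list that camera called or that held at least 3 called genes. Nphs1, Wt1, Podxl, Synpo, Lepr, Nos3 and Rpl10a are always included as a check of the labels. For the other comparisons it takes the 5 higher and 5 lower genes with the lowest p. Genes named outside the rule are said to be so, and some genes within it are not used here.

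Alternatives covered DESeq2 1.42.0, other size factors, limma on the deposited FPKM, other filters, other sets of libraries in the fit, a replicate block, marker scores as covariates, genes no lower in TRAP than in kidney, and leaving out each library in turn. The steps were tested on simulated data, with genes and a list shifted by known amounts. Permutation and Fisher tests were computed in R, and plots were drawn with matplotlib 3.10.9 under Python 3.11.15. Single cell or protein data were not used here.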

Results

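The series profiled RNA on podocyte ribosomes in 2 mouse models of diabetes. In the type 2 model, mice lacking the endothelial nitric oxide synthase eNOS and carrying the db/db mutation of the leptin receptor were compared with eNOS-deficient mice at 3 and 6 months of age. In the type 1 model, mice given streptozotocin (STZ), which destroys insulin-producing cells, were compared with untreated mice at 3 weeks (age 3 months) and 24 weeks (age 8 months) of treatment. All diabetic mice of this model received STZ, so effects of the drug itself and of diabetes cannot be told apart in it. The type 2 model had 5 control and 5 diabetic TRAP libraries at 3 months, and 4 control and 3 diabetic libraries at 6 months. The type 1 model had 4 control and 5 diabetic libraries at 3 weeks, and 5 and 5 at 24 weeks. One whole-kidney library of total RNA came from an eNOS-deficient control at 3 months.

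Total counts per library were 19905606 to 28870716 in type 2 controls and 14866828 to 37786025 in diabetic libraries at 3 months. At 6 months they were 16916596 to 29486283 in controls and 6702120 to 22331040 in diabetic libraries. In the type 1 model they were 14005245 to 19099900 in controls and 10673102 to 24685574 in diabetic libraries at 3 weeks, and 14126122 to 17374563 and 10720194 to 18243370 at 24 weeks.

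The comparison of TRAP with whole kidney asks what the pull-down enriched. Genes that define podocytes were far higher in the 5 TRAP libraries of 3-month type 2 controls than in the kidney library. Nphs1, which encodes nephrin of the slit diaphragm (chromosome 7, 30458315 to 30487223), was at 1617 ± 363 CPM (SD, n = 5) against 13.88 CPM in kidney (95% interval 12.53 to 15.33), a ratio of 113. The transcription factor Wt1 was 135 times higher, the actin regulator Synpo 80.2 times and the surface sialomucin Podxl 65.4 times. Of 35 podocyte identity genes measured, 34 were higher in TRAP, with a median ratio of 30.9. Among the 8 genes with the highest ratios were also Ptpro (129), Myom2 (132), Lmx1b (123), Crb2 (122) and Foxd1 (105).

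Markers of other cells were depleted but present. None of 24 proximal tubule markers was higher in TRAP, and their median was 2.54 times lower. Pck1, a gluconeogenic enzyme of the proximal tubule, was 3.09 times lower, yet still stood at 1222 ± 423 CPM (SD, n = 5) in TRAP. Hpd was 3.68 times lower and Ttc36 2.9 times. Medians were 1.89 times lower for endothelial markers, 1.61 times for mesangial and smooth muscle markers and 1.8 times for macrophage markers. Mitochondrially encoded genes were 11.5 times lower at the median, with mt-Rnr1 22.1 times, mt-Rnr2 18.8 times and mt-Cytb 14.9 times lower. Genes of the glomerular basement membrane and its receptors were 2.66 times higher at the median. Rpl10a, which encodes a protein of the large ribosomal subunit, was 2.95 times higher, Lepr 3.07 times lower, and for Nos3 the kidney library lay inside the range of the TRAP libraries. The single kidney library allows no test, and its interval covers counting error only.

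At 3 months, diabetic libraries of the type 2 model had higher lists of complement and inflammatory, fibrosis and p53 genes, and a lower list of proximal tubule markers, at the preset correlation. With an estimated correlation none of the lists called at 3 months was called, nor by fry. C3, the central complement protein (chromosome 17, 57203970 to 57228136), rose from 25.9 ± 5.16 to 318 ± 242 CPM (SD, n = 5 and 5), a log2 change of 3.61 (SE 0.44, adjusted p = 8.6e-05). Slco1a1, an organic anion transporter (chromosome 6, 141907282 to 141946962), fell by 5.78 on the log2 scale (SE 0.71, adjusted p = 0.00014), and Kap, an androgen-regulated gene of the proximal tubule (chromosome 6, 133849851 to 133853762), fell from 3325 ± 275 to 440 ± 254 CPM (SD, n = 5 and 5). In all, edgeR called 685 of 17180 genes, 348 higher and 337 lower, and 2779 had an unadjusted p under 0.05. Of the called genes, 429 were higher in whole kidney than in TRAP, as were 8693 of the 17180 tested.

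Of 36 podocyte identity genes 1 fell, over all genes and adjusted over the list alone: Kirrel, a nephrin-like slit diaphragm gene, with a log2 change of -0.59 (adjusted p = 0.0331). Nphs1 had a log2 change of -0.91 (adjusted p = 0.106) and was not called. The list was lower than other genes (adjusted p = 0.000563), but adjusted p = 0.618 with an estimated correlation. In the glomerular basement membrane list 2 of 22 genes fell, 4 adjusted over the list alone: the integrin Itga3 (-0.71) and the collagen Col4a4 (-0.74). Its camera adjusted p was 0.0309, and adjusted p = 0.618 with an estimated correlation. Among genes at least 4 times higher in TRAP than in kidney, 16 rose and 44 fell of 633. This set was picked by the same control libraries that serve in this comparison, so the choice itself favours falls. Prune2 (3.34) was the only gene among the 8 largest rises that was over 4 times higher in TRAP. Chosen after their values were seen, the ephrin receptor Epha6 rose (1.65), and the glycosyltransferase Mgat5b (-2.51), the class I antigen H2-Q6 (-1.96) and the natriuretic peptide receptor Npr1 (-1.25) fell.

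Complement and inflammatory genes rose in 7 of 29 cases, 17 adjusted over the list alone with 1 lower, among them the endotoxin receptor Tlr4 (2.16) and the chemokines Cxcl1 (2.83) and Cxcl16 (1.67). The list had adjusted p = 3.53e-08 and adjusted p = 0.311 with an estimated correlation. Of 20 genes of TGF-beta and fibrosis 5 rose, 11 adjusted over the list alone, including Tgfb1 (1.09), Tgfb2 (2.04) and Timp1 (3.84), an inhibitor of matrix proteases. Its adjusted p was 3.34e-06, and adjusted p = 0.311 with an estimated correlation. In the p53, apoptosis and senescence list 3 of 20 rose, 5 adjusted over the list alone, with Phlda3 at 3.14 and the cell cycle inhibitor Cdkn1a at 2.34 (camera adjusted p = 0.00108, and adjusted p = 0.311 with an estimated correlation). Immediate-early and heat shock genes rose in 4 of 21 cases, 6 adjusted over the list alone, with Klf4 at 2.09 (adjusted p = 3e-04, and adjusted p = 0.422 with an estimated correlation). Diabetic libraries 4 and 5 scored 6.01 and 6.025 on this list, while 1, 2 and 3 scored 4.938 to 4.994, within the 4.538 to 4.997 of the controls. Actin and focal adhesion genes rose in 5 of 35 cases, 8 adjusted over the list alone, with Zyx at 0.73 and Msn at 0.76 (adjusted p = 0.00108, and adjusted p = 0.422 with an estimated correlation). No cell cycle gene of 21 was called by edgeR or limma, while DESeq2 called 4, 9 had an unadjusted p under 0.05 and all 21 had a positive change (camera adjusted p = 1.41e-05, and adjusted p = 0.311 with an estimated correlation). Ribosomal protein genes had none called of 32 by edgeR, DESeq2 or limma, 2 with an unadjusted p under 0.05, and a median of 0.18 (adjusted p = 0.00282, and adjusted p = 0.618 with an estimated correlation).

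Metabolic genes moved both ways. The cholesterol list held 3 called genes of 20, all lower, and 4 lower and 1 higher adjusted over the list alone. Cyp51 (-1.91), a sterol demethylase, and the isomerase Idi1 (-0.97) were among them. Its camera adjusted p was 0.0202, and adjusted p = 0.422 with an estimated correlation. Of 22 genes of fatty acid oxidation and PPAR targets 4 fell and 1 rose, 5 and 3 adjusted over the list alone, and the list was not called. The fatty acid transporter Cd36 (chromosome 5, 17781690 to 17888801) fell by 2.50, and the peroxisomal enzyme Ehhadh fell (-1.19). The metallothioneins Mt1 (1.82) and Mt2 (2.03), which bind metals and share sequence, rose within the oxidative stress list, in which 3 of 25 rose and 1 fell. Glycolysis had 1 riser of 18, the pyruvate dehydrogenase kinase Pdk1 (0.68; list adjusted p = 0.041, and adjusted p = 0.618 with an estimated correlation). In the unfolded protein list 1 gene of 27 rose, while 11 fell and 2 rose adjusted over the list alone (adjusted p = 0.00427, and adjusted p = 0.469 with an estimated correlation). Of 12 mitochondrially encoded genes edgeR and limma called none and DESeq2 called 1, with 4 at an unadjusted p under 0.05 (list adjusted p = 0.00363, and adjusted p = 0.618 with an estimated correlation). The interferon and circadian lists each held 1 faller, of 28 and 15 genes, and were not called.

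Markers of other cells moved in the same libraries. Proximal tubule genes fell in 7 of 24 cases, 10 adjusted over the list alone, among them the amino acid transporter Slc7a13 (-2.72), Cyp4b1 (-2.19; chromosome 4, 115624725 to 115647723) and the urate transporter Slc22a12 (-1.51). The list had adjusted p = 3.53e-08, and adjusted p = 0.422 with an estimated correlation. Mesangial and smooth muscle markers rose in 3 of 12 cases, 6 adjusted over the list alone, with the smooth muscle genes Tagln (2.51) and Acta2 (1.71; list adjusted p = 0.000257, and adjusted p = 0.311 with an estimated correlation). Parietal epithelial markers rose in 2 of 7 cases, among them Cd44 at 2.35 (adjusted p = 0.0386, and adjusted p = 0.542 with an estimated correlation). Of 15 macrophage markers edgeR and limma called none, DESeq2 called 5, 7 had an unadjusted p under 0.05 and 5 rose adjusted over the list alone (list adjusted p = 0.0121, and adjusted p = 0.618 with an estimated correlation). Macrophage markers turned lower without diabetic 4 and 5 (adjusted p = 0.156). By exact permutation of library scores, the proximal tubule score differed by -0.67 (p = 0.0159), the mesangial score by 0.77 (p = 0.00794, the smallest this design allows), the macrophage score by 0.63 (p = 0.405) and the podocyte score by -0.30 (p = 0.183). The lowest p of the 44 after adjustment was 0.0786. Diabetic libraries 4 and 5 had the highest macrophage scores of their group (3.94 and 3.03), and without both, a choice made after seeing the data, 418 genes were called and the podocyte, immediate-early, mesangial, parietal, mitochondrially encoded and unfolded protein lists were no longer called. The count of 685 was 404 without control 4 and 451 without control 5, 341 with the proximal tubule score as a covariate, and 259 when testing only genes no lower in TRAP than in kidney.

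**Figure D1:**
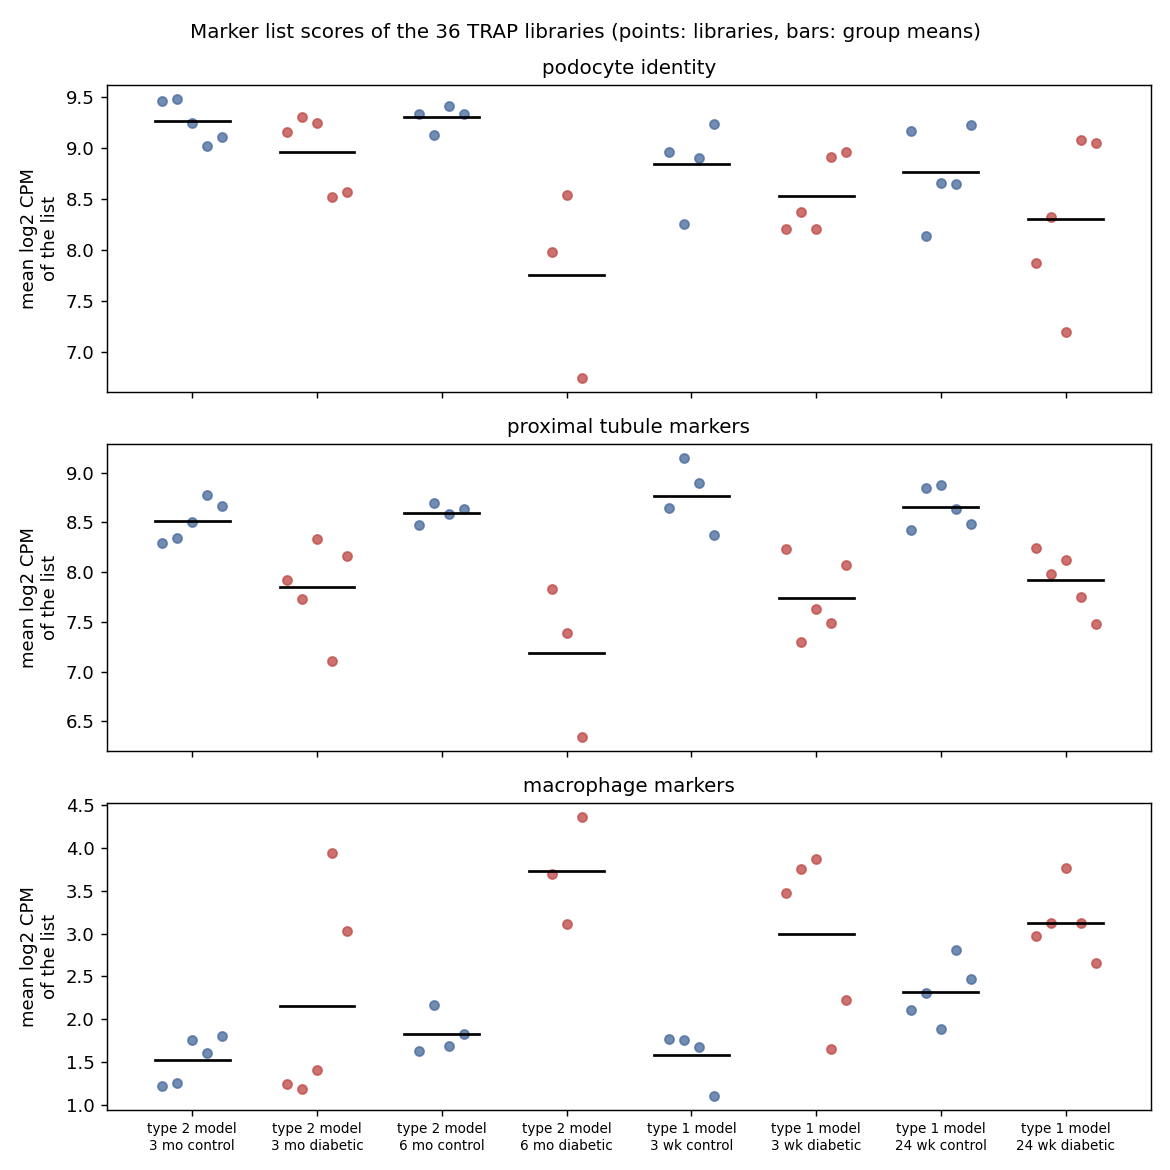
Mean log2 CPM of the podocyte identity, proximal tubule and macrophage lists (vertical axes) in the 36 TRAP libraries by group, with points for libraries and bars for group means. Podocyte scores of the 6-month diabetic libraries averaged 7.76 against 9.3 in their controls, and their macrophage scores averaged 3.72 against 1.83.

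At 6 months, the diabetic libraries of the type 2 model had lower podocyte genes across the list, and higher genes of complement, the p53 list, fibrosis and immune cells. Nphs1 fell from 1498 ± 177 to 284 ± 167 CPM (SD, n = 4 and 3), a log2 change of -2.39 (SE 0.39, adjusted p = 0.000576). C3 rose from 56.1 ± 11.4 to 1193 ± 500 CPM (SD, n = 4 and 3), a log2 change of 4.43 (SE 0.52, adjusted p = 8.4e-05). Kap (-4.41), Slco1a1 (-7.38) and the organic anion transporter Slc22a7 (-4.64) fell. Called genes numbered 3934 of 17180, of which 1922 rose and 2012 fell, and 6336 had an unadjusted p under 0.05. Of those called, 2135 were higher in whole kidney than in TRAP.

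Of 36 podocyte identity genes 30 fell and none rose, 32 adjusted over the list alone. Beside Nphs1, the scaffold Magi2 (-2.18), the phosphatase Ptpro (-2.42), Wt1 (-1.59), Podxl (-1.67) and Synpo (-1.35) fell. The list had adjusted p = 3.24e-14, adjusted p = 0.384 with an estimated correlation and fry adjusted p = 0.00632. Without diabetic library 3, which had the lowest total and the lowest podocyte score (6.75), 23 of the 36 were called lower, at a median of -1.02 instead of -1.35. With the podocyte score as a covariate, chosen after seeing the data, Wt1 (0.36), Podxl (0.051) and Synpo (0.17), all members of that score, turned positive. Among genes at least 4 times higher in TRAP than in kidney, 328 of 633 fell and 5 rose. Mgat5b (chromosome 11, 116918863 to 116986948) fell by 4.06. Chosen after their values were seen, the potassium channel gene Kcng2 (-2.93), neuroglobin Ngb (-3.06), Astn2 (-3.02) and the plasminogen activator Plat (-2.51) fell, while Prune2 rose (1.31). In the glomerular basement membrane list 9 of 22 fell and 7 rose, the same numbers adjusted over the list alone, with falls of Itga3 (-1.21), nephronectin Npnt (-1.51) and the laminin Lamb2 (-1.33), and the list was not called.

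Genes of the complement and inflammation list rose in 13 of 29 cases and fell in 2, 18 and 3 adjusted over the list alone, with the adhesion molecule Vcam1 at 3.63 and Cxcl16 at 1.94, and the complement factor Cfb at -1.39. The list had adjusted p = 8.2e-06, and adjusted p = 0.384 with an estimated correlation. The p53 list had 8 risers and 1 faller of 20, 9 and 1 adjusted over the list alone, including Cdkn1a (3.74), the stress cytokine Gdf15 (3.27) and the apoptosis gene Pmaip1 (2.51; adjusted p = 0.00998, and adjusted p = 0.384 with an estimated correlation). Cell cycle genes rose in 8 of 21 cases, also adjusted over the list alone, with Mcm3 at 2.07 and Mki67 at 4.05 (adjusted p = 0.00183, and adjusted p = 0.384 with an estimated correlation). Of the TGF-beta list 7 of 20 rose and 2 fell, 13 and 2 adjusted over the list alone, with Tgfb1 (1.26) and its receptor Tgfbr1 (1.20) higher and Bmp7 lower (-1.10; adjusted p = 0.00646, and adjusted p = 0.468 with an estimated correlation). Immediate-early and heat shock genes rose in 5 of 21 cases and fell in 3 (adjusted p = 0.0223, and adjusted p = 0.52 with an estimated correlation).

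Genes of protein folding in the endoplasmic reticulum fell: in the unfolded protein list 16 of 27 fell and 1 rose, 16 and 4 adjusted over the list alone, with the chaperone Hsp90b1 at -1.55 and Pdia4 at -1.76 (adjusted p = 6.57e-05, and adjusted p = 0.384 with an estimated correlation). Nuclear-encoded oxidative phosphorylation fell in 15 of 39 cases, 21 adjusted over the list alone, with Sdhb at -1.05 and Uqcrc2 at -0.93 (adjusted p = 9.57e-09, and adjusted p = 0.468 with an estimated correlation). The list nuclear-encoded oxidative phosphorylation turned higher with the proximal tubule score (adjusted p = 0.566) or the podocyte score (0.032) as a covariate, and so did Sdhb with the podocyte score (0.078). Of 12 mitochondrially encoded genes 3 fell, among them mt-Co1 at -1.31 (adjusted p = 0.0431, and adjusted p = 0.702 with an estimated correlation). Glycolysis genes rose in 6 of 18 cases and fell in 1, with hexokinase Hk2 at 4.15 (adjusted p = 0.0322, and adjusted p = 0.482 with an estimated correlation). Circadian clock genes fell in 4 of 15 cases, 7 adjusted over the list alone, with Dbp at -2.10 and Nr1d1 at -2.60 (chromosome 11, 98767932 to 98775333; adjusted p = 0.0185, and adjusted p = 0.384 with an estimated correlation). Nr1d1 overlaps Thra on the opposite strand, and the time of day of collection is not given in the sources used here. Among secreted vascular factors 7 of 19 fell and 3 rose, with Vegfa, which podocytes supply to the glomerular endothelium, at -1.26, Angptl2 at -2.45 and Pdgfa at 1.47, and the list was not called. Other lists that were not called held members that moved both ways: actin (8 rose and 8 fell of 35), cholesterol (3 and 5 of 20, with Cyp51 at -2.24), fatty acid oxidation (5 and 2 of 22, with Plin2 at 1.29), interferon (2 and 1 of 28, with Cd74 at 1.41) and ribosomal proteins (2 and 2 of 32). Rpl10a fell (-1.10), Nos3 rose (1.25), and Lepr had -0.52 (adjusted p = 0.393).

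Markers of most other cell types differed in the same libraries. Macrophage markers rose in 10 of 15 cases, 13 adjusted over the list alone, with Itgam at 3.34 and the lysozyme Lyz2 at 2.42 (adjusted p = 1.13e-05, and adjusted p = 0.434 with an estimated correlation), and the list turned lower with the podocyte score as a covariate (0.563). Fibroblast markers rose in 4 of 8 cases, with the collagen Col1a1 at 3.75 (adjusted p = 0.0131, and adjusted p = 0.468 with an estimated correlation), and 1 of 6 lymphocyte markers rose (adjusted p = 0.0112, and adjusted p = 0.461 with an estimated correlation). Mesangial markers rose in 7 of 12 cases (adjusted p = 0.00257) and parietal epithelial markers in 5 of 7, with Cd44 at 2.60 (adjusted p = 0.00394), each with adjusted p = 0.384 with an estimated correlation. Of 13 collecting duct markers 2 rose (adjusted p = 0.0322, and adjusted p = 0.468 with an estimated correlation). Proximal tubule markers fell in 15 of 24 cases, 16 adjusted over the list alone, with Slc7a13 at -3.70 (adjusted p = 5.76e-09, and adjusted p = 0.384 with an estimated correlation), and 4 of 11 loop and distal tubule markers fell without a call of the list. By exact permutation the podocyte score differed by -1.54, the proximal tubule score by -1.41, the macrophage score by 1.89, the fibroblast score by 1.22 and the parietal score by 1.19, each at p = 0.0286, the smallest that 4 against 3 libraries allow. The count of 3934 was 1932 without diabetic library 3, and 88 with the proximal tubule score as a covariate, 132 with the podocyte score as a covariate chosen after seeing the data. It was 2326 when only these groups were fitted, and 1806 when testing only genes no lower in TRAP than in kidney. Neither score overlapped between the groups (tubule 6.35 to 7.84 in diabetic and 8.48 to 8.7 in control libraries, podocyte 6.75 to 8.54 and 9.13 to 9.41). The counts with these covariates therefore cannot tell cell mixture from diabetes.

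**Figure D2:**
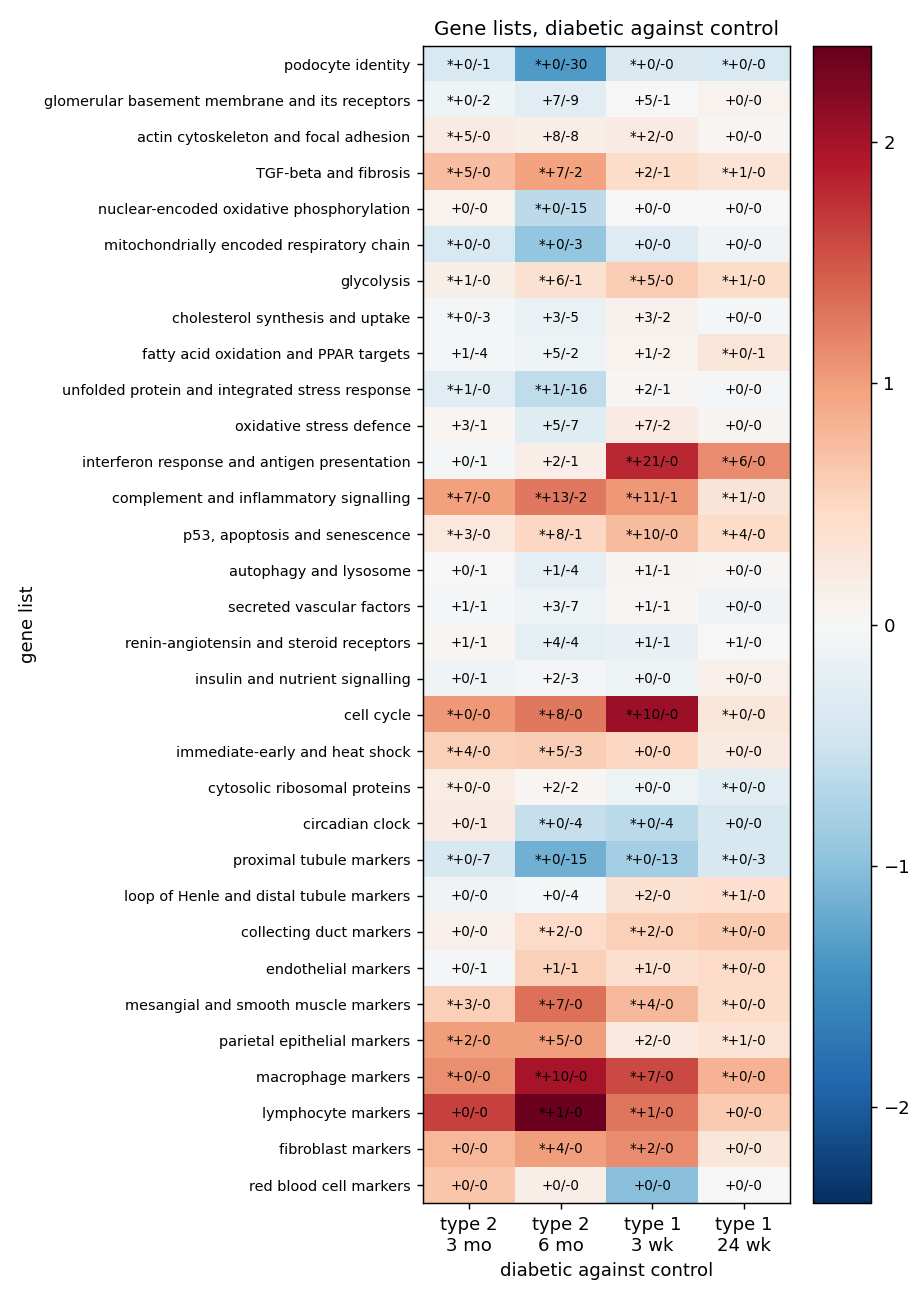
Median log2 fold change of each of 32 gene lists (vertical) in the 4 diabetic comparisons (horizontal), coloured on a scale of log2 units, with an asterisk where camera called the list at the preset correlation and the numbers of called members that rose and fell. The podocyte list had 30 members lower at 6 months of the type 2 model, 1 at 3 months and none in the type 1 model, and the interferon list had 21 higher at 3 weeks of the type 1 model.

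At 3 weeks of STZ, diabetic libraries of the type 1 model had higher genes of antigen presentation and interferon response, cell division, the p53 response and glycolysis, and lower proximal tubule genes. Cd74, the invariant chain of class II antigen presentation (chromosome 18, 60803848 to 60812646), rose from 93.2 ± 19.8 to 492 ± 68.6 CPM (SD, n = 4 and 5), a log2 change of 2.36 (SE 0.39, adjusted p = 0.00111). Ugt1a2, a glucuronidation enzyme (chromosome 1, 88200601 to 88218997), rose from 0.87 ± 0.91 to 152 ± 94.6 CPM (SD, n = 4 and 5). It shares exons with other genes of its family and overlaps others on the opposite strand. Slco1a1 (-6.76) and Kap (-4.01) fell. Called genes numbered 1058 of 16279, of which 616 rose and 442 fell, and 3394 had an unadjusted p under 0.05. Of those called, 751 were higher in whole kidney than in TRAP.

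Of 28 interferon and antigen presentation genes 21 rose and none fell, 26 adjusted over the list alone, with H2-Aa at 2.06, the interferon regulator Irf7 at 2.34 and B2m at 1.93. The list had adjusted p = 2.68e-22, adjusted p = 0.0591 with an estimated correlation and fry adjusted p = 0.000276, and its class I and II genes share sequence. Cell cycle genes rose in 10 of 21 cases, 13 adjusted over the list alone, with Mki67 at 2.35, Top2a at 2.60 and Rrm2 at 2.78, and the call held with an estimated correlation (adjusted p = 8.38e-13 and 0.00496). The p53 list rose in 10 of 20 cases, 11 adjusted over the list alone, among them the cyclin Ccng1, Mdm2, the ligase that limits p53, at 0.74 and Zmat3 at 0.78, and this call held too (2.7e-08 and 0.0039). Complement and inflammatory genes rose in 11 of 28 cases and fell in 1, with C3 at 2.51 and Vcam1 at 2.03 (adjusted p = 1.56e-06, and adjusted p = 0.094 with an estimated correlation). Glycolysis genes rose in 5 of 18 cases, 12 adjusted over the list alone, with Hk2 at 2.68 and the phosphofructokinase Pfkp at 1.42 (adjusted p = 2.84e-08, and adjusted p = 0.176 with an estimated correlation). Circadian genes fell in 4 of 15 cases, with Hlf at -1.11 and Per2 at -1.05 (adjusted p = 0.0217, and adjusted p = 0.176 with an estimated correlation). Actin genes rose in 2 of 35 cases, with Msn at 1.30 (adjusted p = 0.0478, and adjusted p = 0.555 with an estimated correlation).

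No podocyte identity gene of 36 was called, over all genes or adjusted over the list alone, by edgeR, nor by limma on FPKM. DESeq2 called 1 lower, and 3 were lower and 1 higher at an unadjusted p under 0.05. Nphs1 had -0.77 (adjusted p = 0.172), and the list podocyte identity was lower than other genes (adjusted p = 0.00279, and adjusted p = 0.746 with an estimated correlation), turning higher without diabetic 1, 2 and 3 (0.449). In the basement membrane list 5 of 22 rose and 1 fell without a call of the list: the collagen Col4a2 had 1.20 and Col4a4 -0.75. Genes at least 4 times higher in TRAP than in kidney fell in 6 of 632 cases and none rose, where DESeq2 called 15 lower and 2 higher, limma called none and 76 lower and 4 higher had an unadjusted p under 0.05. The oxidative stress list had 7 risers and 2 fallers of 24, with the quinone reductase Nqo1 at 1.60 and Sod1 at -1.04, and was not called. In the cholesterol list 3 rose and 2 fell of 20, with Sqle at 1.07 and Cyp51 at -1.24, and in the fatty acid list 2 fell and 1 rose of 22, with Cd36 at -2.16. The TGF-beta list had 2 risers, fibronectin Fn1 (2.28) and Thbs1 (1.20), and 1 faller of 20, and the unfolded protein list 2 risers and 1 faller of 27, without a call.

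Proximal tubule markers fell in 13 of 24 cases, 15 adjusted over the list alone and 1 rose, with Cyp4b1 at -2.70 and the gluconeogenic enzyme Pck1 at -2.03 (adjusted p = 4.8e-11, and adjusted p = 0.176 with an estimated correlation). The tubular injury marker Havcr1 rose by 3.96. Macrophage markers rose in 7 of 15 cases, with Lyz2 at 1.75 (adjusted p = 1.2e-06, and adjusted p = 0.176 with an estimated correlation), and mesangial markers in 4 of 12, with Acta2 at 1.20 (adjusted p = 0.00347, and adjusted p = 0.253 with an estimated correlation). Lymphocyte markers had 1 riser of 7 (adjusted p = 0.0474, and adjusted p = 0.176 with an estimated correlation), fibroblast markers 2 of 7 (adjusted p = 0.0231, and adjusted p = 0.334 with an estimated correlation), and collecting duct markers 2 of 13 (adjusted p = 0.00798, and adjusted p = 0.477 with an estimated correlation). By exact permutation the proximal tubule score differed by -1.02 (p = 0.0159), the macrophage score by 1.41 (p = 0.0714; 1.8 and p = 0.0317 with scores by the median of the members) and the podocyte score by -0.31 (p = 0.286). Diabetic libraries 1, 2 and 3 had macrophage scores of 3.47, 3.75 and 3.87, against 1.66 and 2.23 in 4 and 5. They also had collecting duct scores of 5.203 to 5.404 and mesangial scores of 5.014 to 5.118, while 4 and 5 lay within the range of the controls in both (4.097 to 4.665 and 3.495 to 4.458). Chosen after seeing the data, the count of 1058 was 94 without libraries 1, 2 and 3, where the circadian, collecting duct, fibroblast, lymphocyte, macrophage and mesangial lists were no longer called, and 1821 without 4 and 5. It was 695 without control 1, and 688, 654 and 611 without diabetic 1, 2 and 3, and 323 with the proximal tubule score as a covariate, 599 when only these groups were fitted, and 192 among genes no lower in TRAP than in kidney.

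At 24 weeks of STZ, fewer genes were called than at 3 weeks, and C3 and interferon genes were among those that rose. C3 rose from 90.6 ± 55.7 to 467 ± 272 CPM (SD, n = 5 and 5), a log2 change of 2.37 (SE 0.39, adjusted p = 0.00358). Ugt1a2 (6.01), the fatty acid hydroxylase Cyp4a14 (3.33) and the vitamin D binding protein Gc (2.69) rose. Slco1a1 (-5.52), Kap (-4.68) and Cyp7b1, an oxysterol hydroxylase (-3.51), fell. Called genes numbered 146 of 16279, of which 73 rose and 73 fell, and 1745 had an unadjusted p under 0.05. Of those called, 129 were higher in whole kidney than in TRAP.

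Interferon and antigen presentation genes rose in 6 of 28 cases, 19 adjusted over the list alone, with Irf7 at 2.60 and Ifit1 at 2.11 (adjusted p = 3.87e-17, and adjusted p = 0.194 with an estimated correlation). Diabetic library 3, which had the highest macrophage score (3.766) and the lowest podocyte score (7.196) of its group, scored 6.268 on this list, against 4.535 to 5.155 in the other diabetic libraries and 3.795 to 4.541 in controls. The p53 list rose in 4 of 20 cases, 8 adjusted over the list alone, with Zmat3 at 0.80 and Gdf15 at 2.50, and its call held with an estimated correlation (adjusted p = 1.49e-08 and 0.00307). Glycolysis had 1 riser of 18, Pfkp at 1.46, and 6 adjusted over the list alone (adjusted p = 2.45e-07, and adjusted p = 0.354 with an estimated correlation). In the fatty acid list Cd36 fell and was the only member called by edgeR, where DESeq2 called 3 higher and 1 lower and limma 1 and 1, while the list was called higher with a median of 0.30 (adjusted p = 0.0106, and adjusted p = 0.507 with an estimated correlation). Of the complement list 1 of 28 rose (adjusted p = 0.00538), of the TGF-beta list 1 of 20 (0.0107), and of the cell cycle list none of 21 by edgeR and 1 by DESeq2 (0.0284), each with adjusted p = 0.354 with an estimated correlation. Ribosomal protein genes had none called of 32 by edgeR, DESeq2 or limma, 9 lower at an unadjusted p under 0.05, and a median of -0.28 (adjusted p = 7.7e-09, and adjusted p = 0.354 with an estimated correlation). No podocyte identity gene of 36 was called by edgeR, DESeq2 or limma, 3 were lower at an unadjusted p under 0.05, and Nphs1 had -0.57 (adjusted p = 0.561). The list podocyte identity was lower than other genes (adjusted p = 1.08e-06, and adjusted p = 0.48 with an estimated correlation), and turned higher without diabetic 1, 2 and 3 (0.00591), a choice made after seeing the data. Of 632 genes at least 4 times higher in TRAP than in kidney edgeR called none, DESeq2 called 4 lower, and 42 lower and 6 higher had an unadjusted p under 0.05.

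Proximal tubule markers fell in 3 of 24 cases, 8 adjusted over the list alone: Cyp4b1 (-1.84), Kap and the urea cycle enzyme Ass1 (-1.09; list adjusted p = 5.16e-07, and adjusted p = 0.354 with an estimated correlation). Calb1 of the distal tubule rose (1.05), the only one of 11 loop and distal tubule markers called by edgeR, where DESeq2 called 2 higher and limma none (adjusted p = 0.001), and none of 13 collecting duct markers was called by edgeR, DESeq2 or limma, with 6 higher at an unadjusted p under 0.05 (1.08e-05), each list with adjusted p = 0.354 with an estimated correlation. Akap12 rose (1.88) among 7 parietal epithelial markers (adjusted p = 0.00822, and adjusted p = 0.194 with an estimated correlation). Of 15 macrophage markers edgeR called none and DESeq2 called 1, with 4 at an unadjusted p under 0.05 (list adjusted p = 2.33e-05, and adjusted p = 0.354 with an estimated correlation). No tool called any of 15 endothelial (list adjusted p = 0.000542) or 12 mesangial markers (0.0433), with 4 and 3 at an unadjusted p under 0.05, each list with adjusted p = 0.422 with an estimated correlation. By exact permutation the proximal tubule score differed by -0.74 (p = 0.00794), the macrophage score by 0.81 (p = 0.0159), the collecting duct score by 0.59 (p = 0.0159) and the podocyte score by -0.46 (p = 0.31). With scores by the median of the members the macrophage difference was 0.48 (exact permutation, p = 0.103). The count of 146 was 76 without control 2, 67 without control 3, and 74, 69, 262 and 79 without diabetic 2, 3, 4 and 5. Without diabetic libraries 1, 2 and 3, chosen after seeing the data, it was 7, and the fatty acid, cell cycle, ribosomal, glycolysis, loop and distal tubule, endothelial, mesangial and parietal lists were no longer called. It was 55 with the proximal tubule score as a covariate, 82 with a replicate block, and 5 among genes no lower in TRAP than in kidney. Of 32 called genes on the list of named genes, which includes genes chosen after values were seen, none kept its direction and its call under every alternative run.

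**Figure D3:**
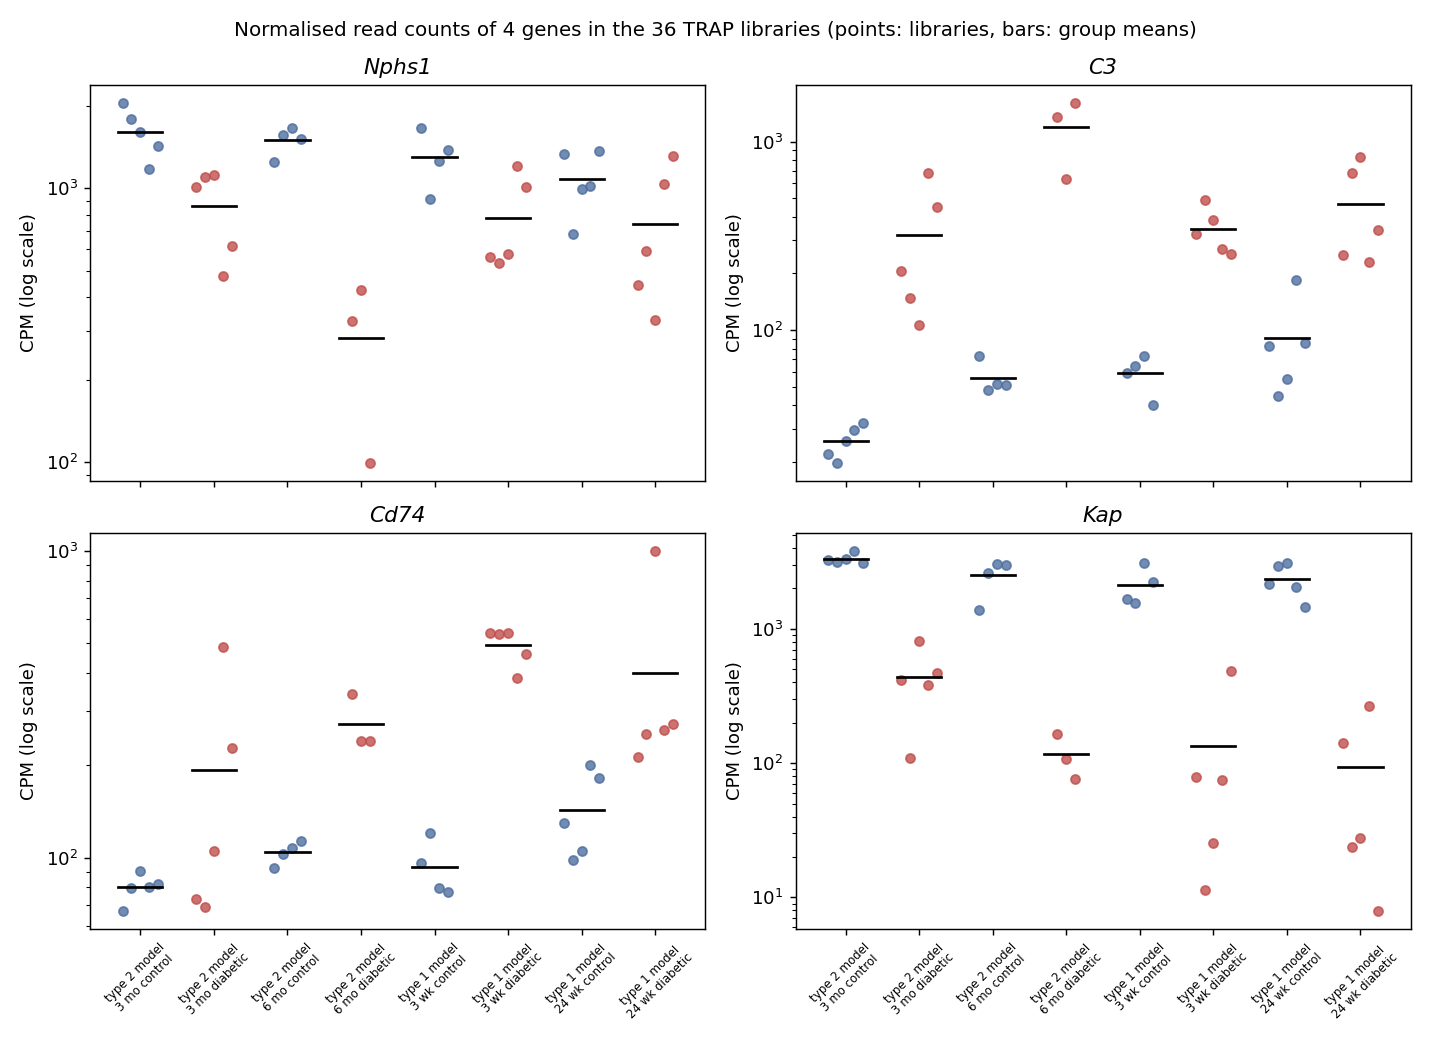
Normalised read counts (CPM, log scale) of Nphs1, C3, Cd74 and Kap in the 36 TRAP libraries by group, with points for libraries and bars for group means. Nphs1 averaged 284 CPM in 6-month diabetic libraries against 1498 in their controls, and Cd74 averaged 492 CPM at 3 weeks of STZ against 93.2.

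Several lists were called in none of the 4 diabetic comparisons: oxidative stress defence, autophagy and lysosome, secreted vascular factors, renin-angiotensin and steroid receptors, insulin and nutrient signalling, and red blood cell markers. Some of their members changed at 6 months of the type 2 model. Of 25 oxidative stress genes 5 rose and 7 fell. Of 20 autophagy and lysosome genes 4 fell and 1 rose, with the protease Ctsl at -0.99 and Ctsd at 0.99. Of 15 renin-angiotensin and steroid receptor genes 4 rose and 4 fell, with Ace at -1.42 and angiotensinogen Agt at 1.20. Of 20 insulin and nutrient genes 2 rose and 3 fell, with Irs2 at -1.07 and the mTOR inhibitor Ddit4 at 2.67. No red blood cell marker of 5 was called by edgeR or limma, while DESeq2 called 1 and 1 had an unadjusted p under 0.05. At 3 weeks of STZ 1 autophagy gene rose and 1 fell, as did 1 and 1 of 18 vascular factors and 1 and 1 of 15 renin-angiotensin genes. At 3 months of the type 2 model 1 of 19 vascular factors and 1 of 15 renin-angiotensin genes rose and as many fell, and 1 autophagy gene and 1 insulin and nutrient gene fell. At 24 weeks of STZ 1 renin-angiotensin gene rose.

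The models and ages shared more called genes than independent genes would share by chance. The chance counts and Fisher's tests below treat genes as independent. Genes can move together, so these p-values do not measure the spread between libraries and can be too small. The 3-month and 6-month type 2 comparisons shared 233 higher genes against 38.9 by chance, and 239 lower genes against 39.5 (Fisher's exact test, adjusted p = 5.81e-138 and 1.04e-145), with 1 gene in opposite directions. The 3-month type 2 and 3-week type 1 comparisons shared 77 higher genes against 13.1 and 112 lower genes against 9.28 (6.71e-38 and 7.32e-92). The 6-month type 2 and 24-week type 1 comparisons shared 45 higher genes against 8.49 and 67 lower genes against 9.01 (2.74e-24 and 5.35e-54). The 3-month type 2 and 24-week type 1 comparisons shared 25 higher genes against 1.57 and 48 lower against 1.54, and the 6-month type 2 and 3-week type 1 comparisons 277 against 70.7 and 192 against 54.4, with 17 in opposite directions. The type 1 comparisons shared 55 higher genes against 2.76 and 60 lower against 1.98. Across genes, which are not independent replicates, log2 changes correlated with r between 0.35 and 0.47. Over genes at least 4 times higher in TRAP than in kidney, r was 0.5 between the type 2 comparisons, 0.25 between the type 1 comparisons and 0.1 to 0.29 between the models. In all 4 comparisons 17 genes rose and 44 fell of 15965 tested in each, against 0.00695 and 0.00524 by chance, and 16 and 43 of them were higher in whole kidney than in TRAP. Among those that rose were C3, Ugt1a2, Krt20, Gc and Spp1, and among those that fell were Slco1a1, Kap, Akr1c14, Cyp7b1, Cd36 and Cyp4b1.

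Whether the diabetic effect changed with age was tested as an interaction within each model. In the type 2 model the lists of podocyte identity, the unfolded protein response and proximal tubule had larger falls at 6 than at 3 months, and macrophage markers larger rises. The oxidative phosphorylation and circadian lists fell at 6 months and were not called at 3 months. Podocyte identity genes had a median interaction of -1.12, with none called over all genes and 24 lower adjusted over the list alone (adjusted p = 1.54e-12, and adjusted p = 0.763 with an estimated correlation). Circadian genes had a median of -0.92 and 6 lower and 1 higher adjusted over the list alone, and the unfolded protein list 11 lower. Both lists, proximal tubule markers and macrophage markers had adjusted p = 0.000983, and oxidative phosphorylation 5.3e-10, each with adjusted p = 0.763 with an estimated correlation. No single gene passed in edgeR, with 3252 at an unadjusted p under 0.05. DESeq2 called 577, and limma on FPKM called 3 and 0 with the 2 pseudocounts. The genes with the lowest p were Fam134c (1.05) and Kcng2 (-1.93), both with adjusted p = 0.0876. The count of 0 became 259 without 3-month diabetic 4, 1911 without 6-month diabetic 2, and 1 without 6-month diabetic 3.

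In the type 1 model, cell cycle genes had smaller rises at 24 than at 3 weeks, with a median interaction of -1.77 over 21 genes and 7 lower adjusted over the list alone. This call held with an estimated correlation (adjusted p = 2.41e-11 and 0.0154). Interferon genes had a median of -0.58 (adjusted p = 4.29e-06, and adjusted p = 0.635 with an estimated correlation), and complement genes -0.49 (adjusted p = 0.00174), while insulin and nutrient genes had 0.18 (0.00304), both with adjusted p = 0.442 with an estimated correlation. Proximal tubule markers had 0.42 (adjusted p = 0.00137, and adjusted p = 0.775 with an estimated correlation), fatty acid genes 0.24 (0.0167, and adjusted p = 0.799 with an estimated correlation) and ribosomal protein genes -0.24 (0.0167, and adjusted p = 0.811 with an estimated correlation). No single gene passed in edgeR, with 1092 at an unadjusted p under 0.05. DESeq2 called 64, and limma on FPKM 4 and 2. The lowest p was that of G6pc, the last enzyme of glucose release (3.00, adjusted p = 0.125). The count of 0 became 1 without 24-week control 2, 24-week control 3, 24-week diabetic 3, 3-week control 1 or 3-week control 4, and 3 without 3-week control 2.

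The early diabetic effects of the 2 models, at 3 months and at 3 weeks of STZ, differed most in interferon genes. Their change was smaller in the type 2 model by a median of 1.69 log2 units (-1.69), with 5 of 28 called lower and 22 adjusted over the list alone (adjusted p = 1.53e-25, and adjusted p = 0.0652 with an estimated correlation). Cell cycle genes had a median of -0.94 and 5 lower adjusted over the list alone (adjusted p = 6.69e-05), and p53 genes -0.44 with 3 called lower and 1 higher (0.00143), both with adjusted p = 0.128 with an estimated correlation. Circadian genes had a median of 1.04 with 3 of 15 called higher (adjusted p = 0.00168, and adjusted p = 0.128 with an estimated correlation). Glycolysis had -0.50 (adjusted p = 5.66e-05, and adjusted p = 0.389 with an estimated correlation), cholesterol genes -0.28 (0.00925, and adjusted p = 0.608 with an estimated correlation) and the unfolded protein list -0.29 (0.00135, and adjusted p = 0.495 with an estimated correlation). Ribosomal protein genes (0.29, adjusted p = 0.000273), proximal tubule (0.32, 0.0225), collecting duct (-0.35, 0.0265) and macrophage markers (-0.47, 0.0386) each had adjusted p = 0.782 with an estimated correlation. Called genes numbered 174 of 18511, 69 higher and 105 lower, with 2586 at an unadjusted p under 0.05. Adamtsl5 had 3.19 (SE 0.43, adjusted p = 0.000156), the vitamin D activating enzyme Cyp27b1 4.55, G6pc 3.07, the aminotransferase Gpt2 -1.80 and the class I antigen H2-D1 -1.62. The models also differ in how diabetes arose, and the labels give no genotype for the type 1 libraries. The count of 174 was 99, 89, 96 and 85 without 3-week control 1 and diabetic 1, 2 and 3. It was 106, 114 and 107 without 3-month control 2, 4 and 5, and 75, 83 and 115 without 3-month diabetic 1, 2 and 5.

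The late effects, at 6 months and at 24 weeks of STZ, differed in lists that fell at 6 months. Podocyte identity genes had a median difference of -0.98, none called of 36 and 6 lower adjusted over the list alone (adjusted p = 2.29e-09, and adjusted p = 0.447 with an estimated correlation). Oxidative phosphorylation genes had -0.59 with 9 lower adjusted over the list alone (adjusted p = 2.2e-13), and the unfolded protein list -0.62 with 2 of 27 called lower and 13 adjusted over the list alone (6e-09), with adjusted p = 0.377 and adjusted p = 0.222 with an estimated correlation. Complement genes had 0.90 with 1 of 29 called (adjusted p = 5.87e-05), loop and distal tubule markers -0.64 (0.000153), autophagy genes -0.20 (0.021), parietal (0.59, 0.0187) and lymphocyte markers (2.10, 0.0151), each with adjusted p = 0.377 with an estimated correlation. Proximal tubule markers had -0.56 (adjusted p = 5.87e-05, and adjusted p = 0.459 with an estimated correlation), macrophage markers were higher (0.00236, and adjusted p = 0.501 with an estimated correlation) and cell cycle genes 0.96 (0.0181, and adjusted p = 0.426 with an estimated correlation). Mesangial (0.80, adjusted p = 0.0075) and fibroblast markers (0.83, 0.004) had adjusted p = 0.381 with an estimated correlation. Interferon genes (-0.95, 0.00169), ribosomal protein genes (0.37, 0.0012), basement membrane genes (-0.43, 0.0279) and mitochondrially encoded genes (-0.90, 0.0196) had adjusted p = 0.519 with an estimated correlation. Called genes numbered 81, 33 higher and 48 lower, with 2802 at an unadjusted p under 0.05. The transporter Slc22a19 had -4.22 (SE 0.56, adjusted p = 0.000114), the exchange factor Net1 1.17 and Pmaip1 1.97. The count of 81 was 12, 34 and 15 without 24-week control 1, 3 and 4, and 31 and 12 without 24-week diabetic 2 and 5. It was 40, 6 and 10 without 6-month control 1, 3 and 4, and 549 and 4 without 6-month diabetic 2 and 3.

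Controls of different ages were compared within each model. In the type 2 model no gene was called between 6 and 3 months in edgeR, with 540 at an unadjusted p under 0.05. DESeq2 called 21 and limma on FPKM called 0 with either pseudocount. Ceacam2 had 1.49 (adjusted p = 0.0677). The unfolded protein list was higher at 6 months with a median of 0.26 and 2 higher adjusted over the list alone (adjusted p = 1.42e-10, and adjusted p = 0.155 with an estimated correlation), as were complement genes (0.31, adjusted p = 0.000281, and adjusted p = 0.865 with an estimated correlation) and circadian genes (0.35, adjusted p = 0.00312, and adjusted p = 0.552 with an estimated correlation).

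In the type 1 model 603 genes were called between controls of 8 and 3 months, 351 higher and 252 lower in the older, with 2851 at an unadjusted p under 0.05. Ribosomal protein genes were higher in the older controls, 11 of 32 called and 17 adjusted over the list alone, with Rps6 at 1.31 (SE 0.15, adjusted p = 2.69e-05). Mitochondrially encoded genes were higher in 4 of 12 cases (adjusted p = 1.05e-05), and mt-Co2 averaged 20.5 CPM in the older and 0.053 CPM in the younger. Fatty acid genes were lower in 2 of 22 cases, 10 adjusted over the list alone (0.000294), and the unfolded protein list in 3 of 27, Hsp90b1 among them, and 1 gene was higher (0.000959). In that list the median was -0.31 while the mean was 0.03. Complement genes had 6 of 28 higher adjusted over the list alone (0.0241). The ribosomal (2.04e-08), mitochondrial, fatty acid, unfolded protein and complement lists each had adjusted p = 0.649 with an estimated correlation. Renin-angiotensin genes were lower in 1 of 15 cases (adjusted p = 0.0156, and adjusted p = 0.177 with an estimated correlation), and lymphocyte markers higher in 1 of 7 (0.046, and adjusted p = 0.337 with an estimated correlation). The count of 603 was 393, 388 and 374 without 24-week control 1, 3 and 4, and 365 and 401 without 3-week control 3 and 4.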

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

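The splits of the libraries were planned before the data were examined, and every other test of an explanation in this part was chosen only after the result it concerns was seen.

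Libraries that stood alone in their group were looked for by Dixon's test at 95%, with 25 measures in each group of at least 4 libraries, 175 tests in all. The 6-month diabetic group of 3 libraries was too small to be tested. It marked 7, and chance marks about 1 in 20, or 8.75 of 175. They were 24-week control 3 of the type 1 model, with 14.1 M counts against 17 to 17.4 M in the others, and 3-month control 4 of the type 2 model, with 20600 genes detected against 19100 to 19500. The 24-week control 2 had 18.4% of its counts on the 18S gene against 7.13 to 10.1%, and 72.8% on protein-coding genes against 84.6 to 89.1%. At 3 weeks of STZ, control 4 had a macrophage score of 1.11 against 1.68 to 1.78, diabetic 5 had a log2 CPM of 1.41 for Lepr against 3.09 to 3.32, and diabetic 4 had -2.65 for Nos3 against 1.62 to 3.03.

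Effects that differed between models or ages by a test of the difference were 174 genes for the early and 81 genes for the late effect of the 2 models. Of the lists that camera called at the preset correlation for such a difference, those also called with an estimated correlation or by fry were circadian clock genes with age in the type 2 model (adjusted p = 0.000983, 0.763 with an estimated correlation and 0.0336 by fry) and cell cycle genes with time in the type 1 model (2.41e-11, 0.0154 and 0.00518). Between the models they were interferon genes (1.53e-25, 0.0652 and 0.0023), p53 genes (0.00143, 0.128 and 0.00604) and cell cycle genes (6.69e-05, 0.128 and 0.0127) for the early effect, and the unfolded protein list (6e-09, 0.222 and 0.00268) for the late effect. Of these 6 lists, only cell cycle genes with time in the type 1 model kept the call with an estimated correlation.

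Other splits of the same libraries into groups of the same sizes were fitted in the same way. For the type 2 model at 3 months 1 of 100 splits, the real one, called as many as 685 genes and the highest other called 2, so chance can be excluded. At 6 months it was 1 of 35, with 3934 against 60 at most, and at 24 weeks of STZ 1 of 100, with 146 against 15, so chance can be excluded for both. At 3 weeks of STZ it was also 1 of 100 with 1058 genes, so chance can be excluded, but another split called 1012. That split set diabetic 1, 2, 3 and control 2 against the rest, and points to a structure of the samples beside diabetes. For the type 1 controls of 2 ages 1 of 100 splits called as many as 603 (0.01), the highest other being 52, which argues against chance.

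For the differences of effects, labels were shuffled within each pair of groups, so a split that leaves one cohort as it was carries its diabetic effect. The early effect had 3 of 100 splits with as many as 174 genes, the highest other calling 1243. Such splits mix diabetic and control libraries and so remove the diabetic effects themselves. They do not keep equal effects in both models, so they cannot exclude chance for a difference between the effects. The late effect had 6 of 100 with as many as 81, the highest other being 2593, and chance cannot be excluded. The changes with age in the type 2 model and with time in the type 1 model called 0 genes by edgeR, and other splits called 3261 and 560 at most. Type 2 controls of 2 ages also had 0, and other splits 1 at most. All 100 of 100 splits reach a count of 0 whatever the data, so the splits decide nothing about chance for these 3. The split with 2593 left the 6-month cohort as it was. The one with 1243 exchanged all labels of the 3-month cohort, and 3-week control 3 with diabetic 4. Both carry the diabetic effect of a cohort, so they decide nothing about a further structure. The counts at an unadjusted p under 0.05 were 3252, 1092 and 540, and DESeq2 called 577, 64 and 21 for these 3.

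The 17 genes that rose and the 44 that fell in all 4 diabetic comparisons were mostly higher in whole kidney than in TRAP (16 and 43). Less tubule RNA in the diabetic libraries would lower the proximal tubule list as far as the shared falling genes. Its median change was 0.243 of theirs at 3 months of the type 2 model, 0.617 at 6 months, 0.5 at 3 weeks and 0.243 at 24 weeks of STZ, but those genes were picked for falling in the same libraries, so these ratios decide nothing. Against genes called lower in the other 3 comparisons the ratio was 0.279 (interval 0.071 to 0.586), 0.621 (0.396 to 0.734), 0.504 (0.261 to 0.772) and 0.334 (0.0663 to 0.63). All 4 intervals lay below the share set as needed if this were the whole cause. By single diabetic library the ratio was at most 0.753 at 3 months, 0.671 at 3 weeks and 0.764 at 24 weeks, also below it, which argues against it as the whole cause there, by a bound added after the ratios were seen. At 6 months a library reached 1, so there it stays open, and a part in the falls stays open throughout. The 16 shared risers higher in kidney had median rises of 2.1 to 2.55 but were picked for rising, so these decide nothing. Tubule transcripts that diabetes changed and that were carried over into the pull-down could give the pattern too: 49.2% of the 61 genes had a ratio of TRAP to kidney within the range of the proximal tubule list, with an interval of 36.1 to 62.3%, against 16.5% of all 8693 genes higher in kidney. That share lies just under the bound set to exclude this explanation and its interval spans the bound, so it stays open, and a change in podocytes themselves remains untested.

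Podocyte markers were lower in the diabetic libraries of the type 2 model at 6 months. A single library of low depth does not account for it, since 23 of 36 members were called lower without diabetic 3. More background RNA of all other cell types would raise tubule markers along with macrophage markers, but the proximal tubule score differed by -1.41 while the macrophage score differed by 1.89, which argues against it. Among genes at least 16 times higher in TRAP than in kidney 117 were called lower and 0 higher by edgeR, with a median of -1.41. A lower share of podocyte RNA raises the markers of all other cell types alike. The marker scores therefore argue only against fewer podocytes or a weaker pull-down with no other change. A larger share of the cell types that rose, lower expression in each podocyte, and a lower podocyte share together with a change in the tubule stay open, as no test here separates them.

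The 603 genes between controls of 3 and 8 months in the type 1 model could stem from age or from a batch of the 3-week cohort. By age, type 2 controls of 3 months should lie nearer to the younger type 1 controls, yet for 77.3% of the genes they lay nearer to the older (interval 73.7 to 80.6%). By batch, both type 2 control groups should lie nearer to the older controls, and this held for 70.6%. Neither value passed the bound set for it by more than its interval. On principal component 2, an axis of variation over genes, the 3-week libraries, control and diabetic, lay at 41.02 to 122.55. All other TRAP libraries lay at 17.25 or below, among them those of the type 2 model at 3 months. These values argue against an age effect common to both models. The labels give no genotype for the type 1 libraries, so a batch and an age effect of the type 1 model alone cannot be told apart. Of 585 genes tested in both models, 53% had the same sign with age in type 2 controls.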

How the results depend on the processing

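Alternatives marked here as chosen after seeing the data are the podocyte score as a covariate, the genes at least 4 times higher in TRAP, and the libraries left out together, and the others were fixed before the data were examined. The cause of a change was not tested unless said. The counts of gene values that follow leave out the genes not used here, which were removed after the results were seen and had a reversed value at 6 months among them. Of 1512 gene values at 3 months of the type 2 model 1271 kept direction and call and 241 lost the call. At 6 months it was 2188 kept, 405 lost and 26 reversed, at 3 weeks of STZ 1560 kept and 230 lost, and at 24 weeks 512 kept and 196 lost. In these comparisons 4, 7, 3 and 3 list values reversed.

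Leaving out each library in turn gave 404 to 737 called genes at 3 months (685 with all), 1932 to 5350 at 6 months (3934), 611 to 1350 at 3 weeks (1058) and 67 to 262 at 24 weeks (146). It gave 0 to 1911 for the change with age in the type 2 model (0 by edgeR), 0 to 3 for the change with time in the type 1 model (0), 75 to 243 for the early difference of the models (174), 4 to 549 for the late one (81), 0 for ages of type 2 controls and 365 to 612 for type 1 controls (603). Called lists ranged from 6 to 12 for the change with age in the type 2 model, 3 to 9 for type 2 controls and 6 to 11 for type 1 controls.

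DESeq2 called 1246 genes at 3 months, 1735 at 3 weeks, 429 at 24 weeks, 577 for the change with age, 64 for the change with time, 462 for the early and 495 for the late difference, 21 for type 2 controls and 1258 for type 1 controls. Limma on FPKM plus 0.1 called 3 for the change with age, 4 for the change with time, 107 for the early and 49 for the late difference, and on FPKM plus 1 it called 2, 115 and 138 for the last 3. It moved the median of all genes by 0.14 and 0.11 at 3 weeks. With no low-count filter the counts were 3 for the change with age, 99 early, 22 late, 2 for type 2 and 368 for type 1 controls, and with a stricter filter 156 late. All 36 libraries in one fit gave 1636 at 3 weeks, 271 at 24 weeks, 14 for the change with time and 1206 for type 1 controls. Only the groups compared gave 2326 at 6 months, 599 at 3 weeks, 9 for type 2 and 291 for type 1 controls.

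Testing only genes no lower in TRAP than in kidney gave 259 at 3 months, 1806 at 6 months, 192 at 3 weeks, 5 at 24 weeks, 105 early, 2 for type 2 and 388 for type 1 controls. This setting drops by construction the called genes that were higher in kidney, which were the larger part in each of the 4 diabetic comparisons. Genes at least 4 times higher in TRAP, chosen after seeing the data and adjusted among themselves, gave 92 at 3 months, 400 at 6 months, and 0 at 3 weeks and 0 at 24 weeks. At 3 months the control libraries of the comparison also defined this set. A replicate block, which pairs libraries by number, gave 403 at 3 months, 2575 at 6 months, 82 at 24 weeks and 1 for the change with time. A pseudocount of 5 gave a median log2 enrichment of podocyte genes of 4.46. No library met the bound for a poor pull-down, so that alternative has no value.

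With the proximal tubule score as a covariate the counts were 341 at 3 months, 88 at 6 months, 323 at 3 weeks, 55 at 24 weeks, 334 early and 3 late. This score did not overlap between diabetic and control libraries at 6 months, 3 weeks or 24 weeks, nor did the podocyte score at 6 months. Lost calls and reversals there cannot tell cell mixture from diabetes. At 6 months Egf (0.33), Foxi1 (-0.48), Ppp1r1a (0.25), Rpl5 (-0.44), Rps6 (-0.21) and Umod (0.036) reversed. The list of proximal tubule markers reversed with its own score as covariate, which follows from the construction, with adjusted p = 0.742 at 3 months, 0.614 at 6 months, 0.557 at 3 weeks, 0.0721 at 24 weeks, 0.863 for the change with age and 0.963 for the early difference. Also reversed were actin genes at 3 weeks (0.153), ribosomal protein genes (0.742) and macrophage markers (0.968) at 3 months, and oxidative phosphorylation at 6 months (0.566).

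With the podocyte score as a covariate, chosen after seeing the data, the counts were 1247 at 3 months, 132 at 6 months, 285 at 24 weeks, 1 for the change with time, 515 early, 1 for type 2 and 1307 for type 1 controls. Reversed at 6 months were Podxl (0.051), Synpo (0.17) and Wt1 (0.36), members of the list that gives the score, and Akap12 (-0.10), Cd3e (-0.11), Ctsd (-0.009), Ddit4 (-0.24), Foxi1 (-0.85), Mki67 (-0.15), Oasl2 (-0.17), Oit1 (-0.67), Pax8 (-0.11), Rpl10 (0.047), Rpl27 (0.42), Rpl5 (-0.43), Rps6 (-0.30), Sdhb (0.078), Slc2a1 (-0.37), Slc4a1 (-1.28) and Tgfbi (-0.58). Lists that reversed at 6 months were collecting duct (adjusted p = 0.451), immediate-early (0.781), lymphocyte (0.775), macrophage (0.563) and oxidative phosphorylation (0.032). For the change with age they were macrophage (0.357), oxidative phosphorylation (0.802) and podocyte (0.802), and for the late difference podocyte (0.702).

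Chosen after seeing the data, leaving out diabetic 4 and 5 at 3 months gave 418 genes and reversed macrophage markers (adjusted p = 0.156). Leaving out diabetic 1, 2 and 3 at 3 weeks gave 94 and reversed the podocyte list (0.449), and leaving out 4 and 5 gave 1821. Leaving out diabetic 1, 2 and 3 at 24 weeks gave 7 and reversed the lists podocyte identity (0.00591) and fatty acid oxidation and PPAR targets (0.327). Without 6-month diabetic 3 and 24-week diabetic 3 the late difference called 1 gene.

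With an estimated correlation camera called 0 lists at 3 months (17 at the preset value), 0 at 6 months (18), 2 at 3 weeks (14), 1 at 24 weeks (16), 0 for the change with age (6), 1 for the change with time (7), 0 early (11), 0 late (17), 0 for type 2 controls (3) and 0 for type 1 controls (7). Fry called 0 lists at 3 months, 12 of 18 at 6 months, 12 at 3 weeks (11 of 14) and 2 at 24 weeks. It gave 1 each with age and time, 3 early, 1 late, 0 for type 2 and 3 for type 1 controls. The proximal tubule covariate gave 11 late, all among the 17. The podocyte covariate gave 8 at 6 months (5 of the 18) and 5 for type 2 controls (with the 3).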

Other observations

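The tests of explanations in this part were chosen only after the results were seen. Genes that fell in the diabetic libraries of both models included several that are known to be higher in male than in female mouse kidney. Cyp4b1 fell in all 4 comparisons (-2.19, -2.62, -2.70 and -1.84), as did Cyp2e1 (-1.32, -1.88, -2.43 and -2.24) and Cyp4a12a (-1.92, -1.85, -1.47 and -1.55), which shares sequence with Cyp4a12b. Odc1 fell at 3 and 6 months of the type 2 model (-1.43 and -1.06), and Gusb was called in none of the 4 by edgeR. Lower androgen action in the diabetic mice is a candidate explanation. Of 24 pairs of 6 male-biased genes and 4 comparisons 58.3% were called lower: 12 of 12 among genes shared by every comparison, and 2 of 12 outside these. The first share rests on genes chosen because they fell, so the data leave the question open. Of 20 pairs of 5 female-biased genes 5% were called higher and 25% lower, among the latter Cyp2a4 in all 4 comparisons.

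Hormone levels were not analysed here, and the labels give no sex. Ddx3y, a gene of the Y chromosome, was at 36.4 to 115 CPM in all 37 libraries. Xist, transcribed from the inactive X chromosome of females, was at most 0.672 CPM except in 6-month diabetic 3 of the type 2 model, with 4.33 CPM (29 counts). Pigr, which carries immunoglobulin across epithelia, took 0.036 to 15.2% of the counts of a TRAP library and was 30.5 times higher in TRAP of 3-month controls than in kidney, a gene named after its values were seen. Lepr, the gene mutated in db/db mice, was not called in the type 2 comparisons (-0.38 and -0.52, adjusted p = 0.668 and 0.393). Nos3, which encodes eNOS, was detected at 3.528 ± 1.235 CPM in 3-month type 2 controls, whose label gives loss of eNOS, and at 6.199 ± 4.802 CPM in 3-week type 1 controls (SD, n = 5 and 4). It rose at 6 months of the type 2 model (1.25). Counts per gene do not show whether a transcript is functional, and Nos3 overlaps genes on the opposite strand, so these values do not decide whether the label holds.

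In simulated data of the same size, edgeR recovered 54% of genes changed 2 times at 3 months, 44% at 6 months, 38% at 3 weeks and 42% at 24 weeks, and 14% and 10% for the changes with age and time. A shifted list was called in each of the 10 comparisons, and none of the 31 other lists was. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often lists of correlated genes are called falsely at the preset correlation.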
